A study of Oryzias melastigma with 6 samples.

How the data were processed

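Small RNA was sequenced from pooled brain, liver, ovary and testis of mature marine medaka, with 1 library for each sex and organ. Per the labels, total RNA was treated with DNase, small RNA was purified on a gel, adapters were ligated to both ends, and the cDNA was amplified by PCR. The submitters' processing notes name CASAVA 1.7.0. The aligner, adapter trimming and annotation behind the files are not given in the sources used here. Each of the 6 deposited files gives exact sequences of 20 to 23 nt, each with its length in nt and an expression value, and no miRNA names.

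The unit of the deposited expression values was taken to be RPM, reads scaled to a library total, as made by the authors, from the values themselves, since the file headers name no unit. Every value in a file was a whole multiple, within a tolerance of 0.02, of the value of 1 read in a fixed library total, and the listed values summed to 2.08% to 24.0% of such a total. The totals so implied, 18.7 to 25.5 M reads (M, mega), were used for depth and for counting intervals alone. Files listed no sequence below 6.00 to 10.03 RPM, and the highest of these minima, 10.03 RPM, served as a common minimum. The reads were PCR products without molecular identifiers, so that Wilson and exact binomial intervals cover counting error only.

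Sequences were assigned to miRNA families by similarity to a hand-written list of 181 conserved vertebrate mature miRNAs from 129 family arms, with at most 2 mismatches, a shift of the 5' end of at most 3 nt and an overlap of at least 17 nt. References for miR-146, miR-212 and miR-15 were added after unassigned sequences had been seen. In a check, 0 of 10000 random sequences and 900 of 905 references with a substitution (99.4%) were assigned to a family. Of 1571 sequences in the 6 files, 1057 went to 113 family arms, 5 tied between families were left out, and 383 stayed unassigned; the rest matched adapter, tRNA or rRNA (14 references). RPM were summed over the sequences of a family arm, so paralogues with like sequences were not told apart, and miRNAs outside the list or longer than 23 nt were not analysed here. No genome was used, and no positions are given.

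The tests were chosen before the data were examined, as was a fallback for files without counts, which was applied: limma on log2(RPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. In the fits, values under the common minimum, unlisted ones included, were raised to it, a choice made after the files were seen and before any fit. In fits and enrichment counts on rescaled values the highest scaled value of this minimum over the 6 libraries was used. It was 28.15 when scaled to miRNA reads and 27.36 with median-of-ratios scaling. Means and sums of RPM count unlisted sequences as 0. Any family above the minimum in at least 1 fitted library was tested; the first run asked for 2 libraries, and the planned absence of a filter was then restored. Brain and liver were compared on 4 libraries. The gonads were compared with each of the other organs on all 6 libraries with a shared spread, and sex was tested on the 4 brain and liver libraries with organ and sex as terms. With 1 pooled library per group the p-values measure the difference against the spread between the sexes, not between fish. Families at the minimum in both libraries of an organ show no spread there. Simulated data had the same numbers of families and libraries, no listing minimum, and spreads drawn at random from the female-male differences in brain and liver. These differences were taken after values were raised to the minimum, so families at it in both libraries of an organ gave spreads near 0. Such spreads can make changes easier to recover. With 10 families changed by each of 1, 2 and 4 log2 units at once, 1.26% to 1.87% of unchanged families were called. Of changes of 1 log2 unit 51.7% to 69.0% were recovered. These rates do not cover the wider spread between ovary and testis (SD of log2 ratios over families 1.39, against 0.42 in brain and 0.95 in liver).

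Female and male libraries were compared within each organ by the ratio of RPM with an exact conditional binomial interval (95%), for families with at least 50 RPM in the higher library and at least 20 reads over both. Fold bounds for unlisted families divide the top sequence of the family in the lowest library of the higher organ by the highest listing minimum of the other. A family was called enriched in an organ when every library of it was at least 4-fold above every library of the others, with at least 50 RPM. The families named were, for each test, the 12 with the largest fold in each direction past the threshold, with at least 50 RPM in the higher organ and no overlap between libraries; for each ratio, the 10 largest in each direction; the 10 most abundant families of each library; and members of the lists.

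The lists, fixed before the data were examined, were neuronal, hepatic and gut, germline and gonadal, muscle, blood cells, endothelium and vascular smooth muscle, fibroblast and mesenchyme, epithelium and skin, retina and sensory cells, pancreas, Hox cluster, let-7 and a fish stress-linked cluster. A family can be a marker of a named cell type and still be made by others in the organ. For ratios, a list's median was set against 10000 random lists of the same size and like mean level, with unlisted values at the minimum. These percentiles were not adjusted for the number of lists.

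The alternatives tried were median-of-ratios scaling, scaling to the total of miRNA reads with and without the most abundant families, other filters, pseudocounts of 0.1 and 10, unlisted values at 0, 2-fold and 10-fold bounds and minima of 10 reads or 200 RPM, the highest sequence of each family, only exact references, each exact sequence on its own, sex as a block, a limma fit of ovary against testis, 1 library each, with its spread borrowed from brain and liver, other sets of libraries, and each library left out in turn. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.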

Results

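The series profiled small RNA in 3 organs of sexually mature marine medaka, a small saltwater fish, to describe which microRNAs (miRNAs) each organ holds in each sex. Sequencing of pooled tissue gave 6 libraries, 1 for each sex and organ: female brain, male brain, female liver, male liver, ovary and testis. No group was replicated, so the female and the male library stood for an organ, with ovary and testis standing for the gonads (n = 2 libraries per organ). The deposited values implied totals of 22.7 M reads in female brain, 20.2 M in male brain, 18.9 M in female liver, 18.7 M in male liver, 22.9 M in ovary and 25.5 M in testis (M, mega). Sequences of 20 to 23 nt were listed above a minimum that lay between 6.002 and 10.03 RPM, or 112 to 256 reads, depending on the library. An unlisted sequence therefore lay under that minimum, which does not show that it was absent.

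Brain libraries held the highest share of listed miRNA. Sequences assigned to miRNA families held 23.1% of all reads in female brain (95% Wilson interval 23.07 to 23.11) and 20.98% in male brain (20.965 to 21.001). The share was 1.82% in female liver (1.81 to 1.83), 1.97% in male liver (1.97 to 1.98), 2.35% in ovary (2.35 to 2.36) and 1.53% in testis (1.52 to 1.53). The number of family arms with a listed sequence was 104 in female brain, 102 in male brain, 56 in female liver, 64 in male liver, 65 in ovary and 55 in testis. With only sequences at or above the common minimum of 10.03 RPM these were 99, 93, 48, 54, 65 and 55 in the same order. The family let-7-5p, known for its role in developmental timing and differentiation, led in female brain with 37500 RPM, in ovary with 6870 RPM and in testis with 4385 RPM. In male brain the neural miR-9-3p led with 35274 RPM. In liver miR-194-5p, a miRNA of liver and gut epithelium, led with 7055 RPM in females and 6962 RPM in males, or 38.8% (38.6 to 38.9) and 35.3% (35.1 to 35.4) of miRNA reads. The 10 most abundant families held 64.3% of miRNA reads in female brain, 67.5% in male brain, 86.1% in female liver, 81.3% in male liver, 78.1% in ovary and 79.2% in testis.

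**Figure D1:**
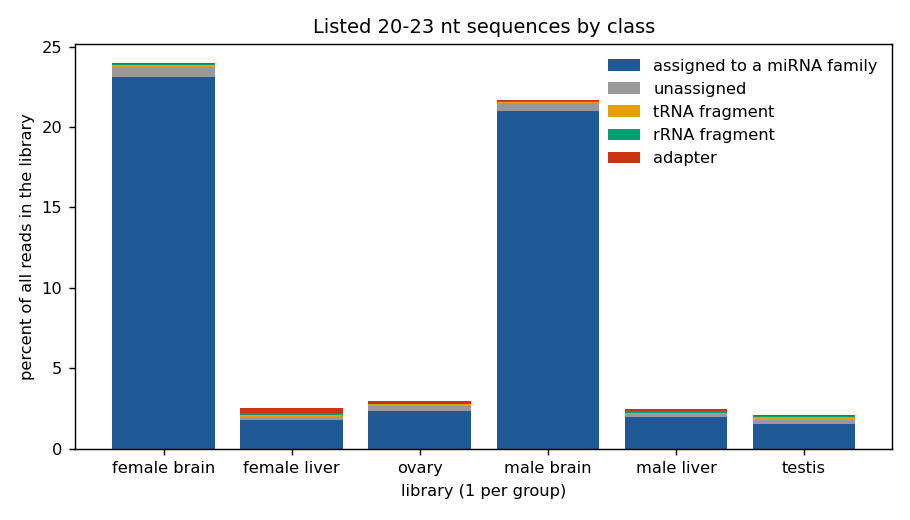
Share of all reads in each of the 6 libraries (y axis, percent) held by listed sequences of 20 to 23 nt, stacked by class; each bar is 1 library. The miRNA part reaches 23.1% in female brain and 20.98% in male brain and stays between 1.53% and 2.35% in the other 4 libraries.

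Brain and liver were told apart by miRNAs long associated with neurons and with hepatocytes. In brain miR-9-3p, a regulator of neural progenitors, reached 33889 ± 1959.6 RPM (mean ± SD, n = 2) and was unlisted in both liver libraries, which puts brain at least 2819-fold higher. The neuronal miR-153-3p reached 17369.6 ± 2689.9 RPM, at least 1641-fold above liver, and miR-124-3p, which represses non-neuronal transcripts in neurons, 5317 ± 655 RPM, at least 355-fold above liver. In liver miR-194-5p reached 7008 ± 65.4 RPM against 8.61 RPM in female brain, and was unlisted in male brain. The hepatocyte miRNA miR-122-5p, which acts in lipid and cholesterol metabolism, reached 1917 ± 133.3 RPM in liver and was unlisted in brain, which puts liver at least 136-fold higher.

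Of the neuronal list, 20 of 21 tested families were higher in brain and none was lower (20 when adjusted over the list alone). Beyond those named above, they included miR-128-3p with a log2 fold of 9.01 ± 0.34 (SE), miR-7-5p with 8.87 ± 0.22, miR-9-5p with 8.62 ± 0.24, miR-132-3p with 8.54 ± 0.11, miR-125-5p with 8.13 ± 0.61, miR-137-3p with 7.67 ± 0.14 and miR-138-5p with 7.53 ± 0.09. Scaled to the total of miRNA reads, 18 of 18 neuronal families remained higher in brain, miR-9-3p by 7.82 ± 0.14 and miR-138-5p by 3.77 ± 0.10. The oligodendrocyte-linked miR-338-3p was higher in brain by 8.05 ± 0.49. Of the hepatic and gut list, 4 of 7 families were higher in liver and 2 higher in brain (4 and 2 when adjusted over the list alone). The 4 were miR-194-5p with a log2 fold of -9.31 ± 0.09, miR-122-5p with -7.44 ± 0.11, miR-192-5p/miR-215-5p with -2.97 ± 0.12 and miR-148-5p with -2.03 ± 0.44, and the same 4 passed after scaling to miRNA reads (3 when adjusted over the list alone), while miR-148-5p missed the threshold with median-of-ratios scaling. The other two were miR-22-3p, with 1.96 ± 0.53 on the deposited scale and -1.54 ± 0.47 after scaling, and miR-101-3p, with 2.34 ± 0.36 and -1.19 ± 0.39, neither of which passed after scaling to miRNA reads; with median-of-ratios scaling miR-22-3p passed as higher in liver, at -0.76 ± 0.19. The fish miRNA miR-722-3p was also higher in liver, with -2.77 ± 0.26, and so was miR-199-5p, a mesenchymal miRNA, with -1.62 ± 0.39.

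The pancreas list was higher in brain in 3 of 3 families (3 when adjusted over the list alone), with 8.17 ± 0.09 for miR-217-5p and 6.63 ± 0.63 for miR-216-5p, which reached 9016 ± 451.2 RPM in brain against 103 ± 71.5 RPM in liver. In the let-7 list both families were higher in brain (2 when adjusted over the list alone), let-7-5p by 4.31 ± 0.18 and let-7-3p by 4.01 ± 0.11. After scaling 1 of 2 was higher, let-7-5p by 0.77 ± 0.18, while let-7-3p stood at 0.28 ± 0.15. The arm let-7-3p was unlisted in both livers, so its fold is a distance to the minimum, which scaling raised to 28.15. With median-of-ratios scaling let-7-5p missed the threshold, at 1.56 ± 0.44, and let-7-3p passed, at 0.93 ± 0.23. The Hox cluster list was higher in brain in its 1 tested member, miR-10-5p, by 4.97 ± 0.11 (1 when adjusted over the list alone) and by 1.23 ± 0.15 after scaling. Retina and sensory cells gave 2 of 5 higher (2 when adjusted over the list alone), with 1 of 2 after scaling (2 when adjusted over the list alone). Several other lists lost calls or turned after scaling to miRNA reads. Over all families 13 calls turned on that scale and 3 with median-of-ratios scaling. Of the germline and gonadal list 7 of 9 families were higher in brain and none lower (7 when adjusted over the list alone), but after scaling 1 of 7 was higher and 3 were lower. Of the muscle list 3 of 3 were higher in brain (3 when adjusted over the list alone) and after scaling 0 of 1. Of the blood cell list 2 of 6 were higher (2 when adjusted over the list alone), miR-144-3p and miR-451-5p, and after scaling 0 of 3 were higher and miR-144-3p was lower, a call that median-of-ratios scaling did not give. Endothelium and vascular smooth muscle gave 3 of 4 higher (4 when adjusted over the list alone), with 0 higher and 2 lower of 4 after scaling (1 lower when adjusted over the list alone). Epithelium and skin gave 3 of 4 higher (1 when adjusted over the list alone; miR-200-3p missed the threshold with sex as a block), with 0 higher and 1 lower of 2 after scaling. Fibroblast and mesenchyme gave 1 higher and 1 lower of 3 (1 and 1 when adjusted over the list alone), with 0 higher and 2 lower after scaling, and the 2 families of the fish stress-linked cluster did not pass on either scale.

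On the deposited RPM scale limma with Benjamini-Hochberg adjustment called 78 of 105 families higher in brain and 6 lower, with a median log2 fold of 2.57. After scaling to the total of miRNA reads the median was 0.07, and 31 of 81 families were higher and 23 lower; with median-of-ratios scaling 37 of 86 were higher and 11 lower. Of the calls made both on deposited RPM and after scaling to miRNA reads, 37 had the same direction and 13 the opposite one. With median-of-ratios scaling these were 42 and 3. The spread in this test is the difference between the female and the male library of each organ. A fitted fold against an unlisted family depends on the listing minimum, and the lower bounds given as at least a fold hold for deposited RPM.

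**Figure D2:**
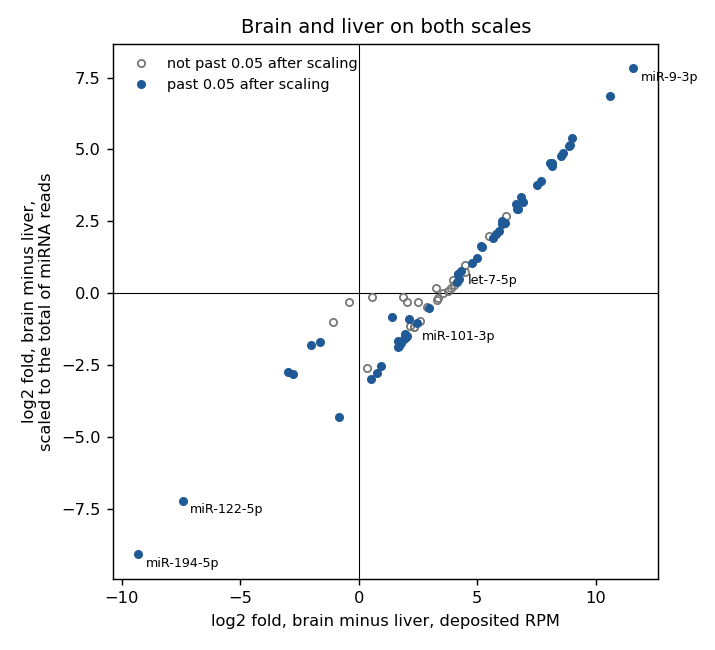
Log2 fold of brain over liver for each of the 81 miRNA families fitted on both scales, from deposited RPM (x axis) and after scaling to the total of miRNA reads (y axis); each point is 1 family, filled where the adjusted p from limma was under 0.05 after scaling. The median moves from 2.57 over the 105 families on the deposited scale to 0.07 after scaling, miR-9-3p stays positive at 7.82, miR-194-5p stays negative at -9.09, and miR-101-3p turns from 2.34 to -1.19.

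The gonads stood apart from brain through miR-202, smooth muscle miRNAs and miR-196. The gonad-associated miR-202-5p reached 1768 ± 724 RPM in the gonads (mean ± SD, n = 2) and was unlisted in brain, which puts the gonads at least 67.9-fold higher. Its other arm, miR-202-3p, reached 149 ± 135.1 RPM, at least 4.66-fold above brain. The smooth muscle miRNAs miR-145-5p and miR-143-3p, which share a cluster, reached 536 ± 17.2 RPM and 1147 ± 144.96 RPM against 63.2 ± 18.7 RPM and 318 ± 25.3 RPM in brain. The Hox cluster miRNA miR-196-5p reached 78.5 ± 22.6 RPM and was unlisted in brain, which puts the gonads at least 5.83-fold higher. In the other direction miR-9-3p was unlisted in ovary and testis, at least 1696-fold below brain.

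By list, 20 of 21 neuronal families were lower in the gonads (20 when adjusted over the list alone), including miR-153-3p by a log2 fold of -10.05 ± 0.42 (SE), miR-128-3p by -9.21 ± 0.31, miR-124-3p by -8.91 ± 0.14, miR-132-3p by -8.54 ± 0.12 and miR-129-3p by -6.92 ± 0.23. After scaling to miRNA reads 16 of 18 remained lower. The widest error among them was that of miR-7-5p, with -5.51 ± 1.69 (adjusted p = 0.0413), which missed the threshold on both other scales and with sex as a block; testis held 601 RPM of it and ovary 20.2 RPM. Its fold was -3.10 without the ovary library and -7.93 without the testis library. Of the germline and gonadal list 2 of 12 families were higher in the gonads, both arms of miR-202, and 7 were lower (2 and 7 when adjusted over the list alone); after scaling 3 of 10 were higher and none was lower. Endothelium and vascular smooth muscle gave 2 higher, miR-143-3p with 1.84 ± 0.29 and miR-145-5p with 3.10 ± 0.40, and 2 lower of 4 (2 and 2 when adjusted over the list alone), with 3 higher and 0 lower after scaling. The Hox cluster list was split, with miR-196-5p higher and miR-10-5p lower by -2.94 ± 0.56 (1 and 1 when adjusted over the list alone), the latter at 0.57 and not passing after scaling. Outside the neuronal list miR-101-3p with -7.03 ± 0.32, miR-103-3p/miR-107-3p with -7.24 ± 0.51 and the endothelial miR-221-3p with -6.99 ± 0.91 were lower in the gonads on both scales. Of the families called on deposited RPM and after scaling to miRNA reads, 8 turned with the scale, among them let-7-5p from -2.62 ± 0.28 to 0.91 ± 0.16, miR-21-5p from -2.31 ± 0.52 to 1.22 ± 0.34, the endothelial miR-126-3p from -2.38 ± 0.32 to 1.14 ± 0.27 and the muscle miRNA miR-1-3p from -1.44 ± 0.31 to 2.07 ± 0.26, while 33 kept their direction. With median-of-ratios scaling 2 of the calls shared with deposited RPM turned and 40 kept their direction, and let-7-5p stood at -0.19 and did not pass.

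In this comparison limma with Benjamini-Hochberg adjustment called 7 of 110 families higher in the gonads and 74 lower on deposited RPM, with a median log2 fold of -2.57. Beyond the 5 named above, the 7 held miR-194-5p with 2.38 ± 0.73 (adjusted p = 0.0413), which missed the threshold with median-of-ratios scaling and when adjusted over the hepatic and gut list alone, and miR-214-3p with 1.96 ± 0.23, whose mean in the gonads lay under 50 RPM and which was named after its value was seen. After scaling to miRNA reads 22 of 89 families were higher and 26 lower, and with median-of-ratios scaling 14 of 92 were higher and 34 lower. Without the female brain library 4 families passed as higher in the gonads. The fold of miR-194-5p was 1.34 without the ovary library and 3.42 without the testis library, and that of miR-202-3p 2.31 and 4.48.

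**Figure D3:**
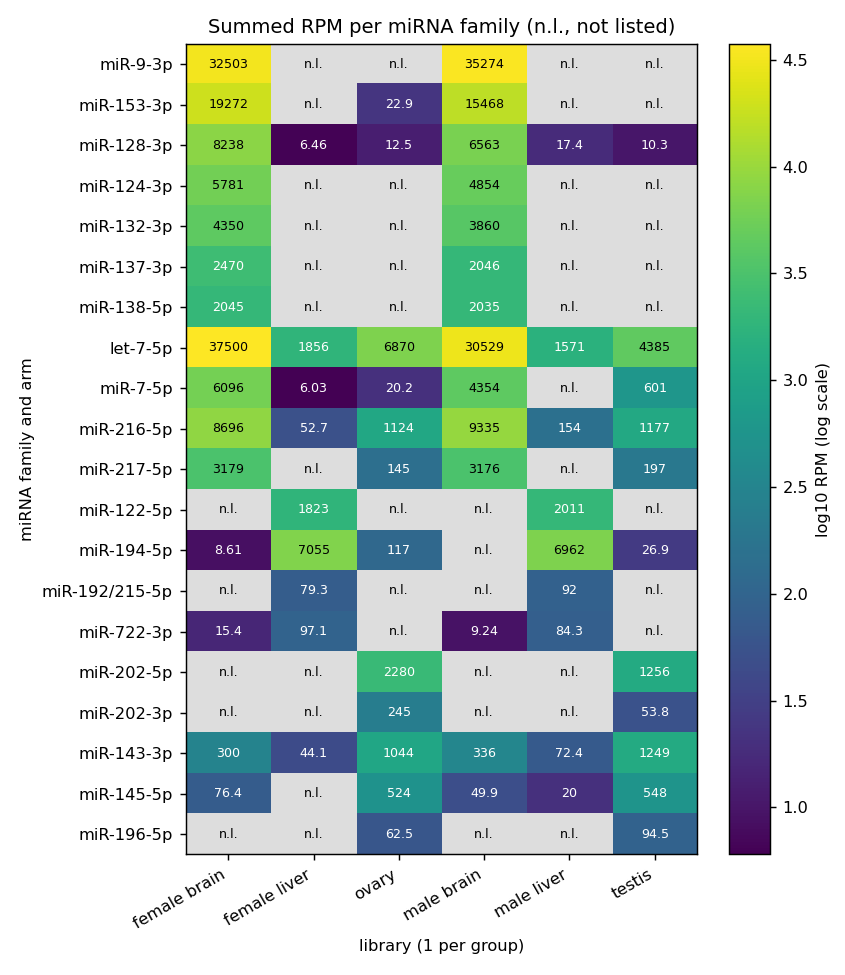
Summed RPM of 20 miRNA family arms (vertical) in the 6 libraries (horizontal), with the RPM printed in each cell and colour on a log10 scale; grey cells marked n.l. were not listed. miR-9-3p was listed in the brain libraries alone (32503 and 35274 RPM), miR-122-5p in the liver libraries alone (1823 and 2011 RPM) and miR-202-5p in ovary and testis alone (2280.0 and 1256 RPM).

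The gonads and liver were set apart by miR-202, smooth muscle and pancreas-linked families on the gonad side and by hepatocyte families on the liver side. In the gonads miR-202-5p was again the family farthest above liver, where it was unlisted, at least 90.4-fold. The smooth muscle pair was higher in the gonads, miR-145-5p by a log2 fold of 5.14 ± 0.40 (SE, n = 2 libraries per organ) and miR-143-3p by 4.31 ± 0.29. In liver miR-122-5p was at least 109-fold above the gonads, where it was unlisted, and miR-194-5p reached 7008 ± 65.4 RPM against 72.1 ± 64.0 RPM (mean ± SD). The list of 7 hepatic and gut families gave 4 lower in the gonads (6 when adjusted over the list alone): miR-122-5p, miR-194-5p, miR-101-3p with -4.69 ± 0.32 and miR-192-5p/miR-215-5p with -2.97 ± 0.13. Pancreas-linked families were higher in the gonads in 2 of 3 cases (2 when adjusted over the list alone), miR-217-5p by 3.95 ± 0.19 and miR-216-5p by 3.66 ± 0.54. The muscle miRNA miR-1-3p was higher in the gonads by 3.03 ± 0.31 and let-7-5p by 1.68 ± 0.28. Of the 21 neuronal families 0 passed (0 when adjusted over the list alone), with miR-7-5p at 3.36 ± 1.69 (adjusted p = 0.398) and miR-125-5p, at 2.39 ± 0.57, passing on the scale of miRNA reads (0 when adjusted over the list alone) and with median-of-ratios scaling. Of 12 germline and gonadal families 1 passed (1 when adjusted over the list alone), miR-202-5p, while miR-202-3p stood at 3.40 ± 0.76 (adjusted p = 0.0568); after scaling to miRNA reads 3 of 10 passed, miR-202-3p and miR-92-3p among them, and miR-202-3p passed with median-of-ratios scaling too.

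Here limma with Benjamini-Hochberg adjustment called 11 of 110 families higher in the gonads and 8 lower, among them miR-196-5p with 2.82 ± 0.23, miR-193-3p with 2.58 ± 0.17, miR-16-5p with 1.68 ± 0.19 and, lower, miR-722-3p with -3.05 ± 0.24, miR-103-3p/miR-107-3p with -3.04 ± 0.51 and miR-33-5p, an intronic miRNA of sterol regulatory genes, with -2.85 ± 0.26. At an unadjusted p under 0.05 there were 29 families, and 33 lay at the listing minimum in both organs. After scaling to miRNA reads 19 of these calls passed in the same direction, and with median-of-ratios scaling 16, without let-7-5p, miR-16-5p and miR-196-5p. The count of families lower in the gonads was 5 without the female brain library and 4 without the male brain library, whose spread enters the test.

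Taken as a description of the 6 libraries, 50 families were enriched in brain, with each brain library at least 4-fold above every other library and at least 50 RPM, against 4 in liver, 4 in both gonads, 2 in ovary and 0 in testis. The liver families were miR-122-5p, miR-192-5p/miR-215-5p, miR-194-5p and miR-722-3p. The families of both gonads were miR-145-5p, miR-196-5p, miR-202-3p and miR-202-5p, and those of ovary were miR-202-3p and the myeloid miR-223-3p. After scaling to miRNA reads 14 families were enriched in brain, all of them among the 50, 5 in liver (with miR-33-5p gained), 6 in both gonads (with miR-143-3p and miR-193-3p gained) and 0 in ovary. The raised minimum of 28.15 on that scale contributes to the fall in brain. For example, miR-132-5p, with 555 and 576 RPM in female and male brain and unlisted elsewhere, no longer reached 4-fold above it.

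Female and male brain were close. Of 81 families with at least 50 RPM in the higher library 77 lay within 2-fold (95.1%), 0 differed by 4-fold or more, and the median female-to-male ratio was 1.18. Of the neuronal miRNAs, miR-9-3p had a ratio of 0.921 (95% counting interval 0.918 to 0.924), and miR-124-3p one of 1.19 (1.18 to 1.20) that turned to 0.927 with median-of-ratios scaling. Female brain held more of the epithelial miR-205-5p, with a ratio of 3.66 (3.45 to 3.88), of miR-19-3p of the miR-17 to 92 cluster with 2.70 (2.60 to 2.81), of the endothelial miR-126-5p with 2.57 (2.34 to 2.82) and of the red cell miRNA miR-451-5p with 2.04 (1.996 to 2.087). Male brain held more of the sensory cell miRNA miR-96-5p, with a ratio of 0.613 (0.602 to 0.623), and of miR-187-3p with 0.677 (0.635 to 0.721). The ratio of miR-29-3p was 0.691 (0.687 to 0.695), but no row of its most abundant male brain sequence was used from female brain, and without that sequence the ratio turned to 1.35. As a list, epithelium and skin had a median log2 ratio of 1.13 over 4 members, at percentile 98.95 of 10000 random lists of that size, and endothelium and vascular smooth muscle one of 0.67 at percentile 92.6. The epithelial members were uneven. While miR-205-5p stood at 3.66 and miR-203-3p was unlisted in male brain, miR-200-3p stood at 1.30, near the median of 1.18. A further member, miR-429-3p, held 29.7 RPM in female and 26.1 RPM in male brain. The list of retina and sensory cells had a median of -0.05 over 5 members, at percentile 3.89.

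The sex difference shared by brain and liver passed the threshold in 0 of 105 families by limma with Benjamini-Hochberg adjustment, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.838. These 2, chosen after their values were seen, were miR-19-3p, higher in females by a log2 fold of 1.17 ± 0.26 (SE), and miR-96-5p, lower by -0.94 ± 0.26, in both organs each. That test has 1 residual degree of freedom, the difference between the sex effects of the organs. A family at the minimum in both livers has a liver difference of 0, so it could not pass whatever its brain difference. Over the 42 families above the minimum in all 4 libraries limma called 0 as well, with a smallest adjusted p of 0.809. With simulated changes the test recovered 82.2% of those of 4 log2 units and 51.7% of those of 1. The simulation changed 10 families by 1, 10 by 2 and 10 by 4 log2 units at once, which eases the adjustment. Its draw held spreads near 0 and no listing minimum, which can raise these shares too. A lone difference may be missed more often, as miR-19-3p at 1.17 ± 0.26 did not pass.

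Female and male liver had fewer families within 2-fold than the brains, 24 of 38 (63.2%), and 2 were at least 4-fold lower in female liver: miR-221-3p, known from endothelium, with a ratio of 0.191 (95% counting interval 0.170 to 0.214), and the leukocyte miRNA miR-142-3p with 0.199 (0.172 to 0.229). They were followed by miR-100-5p with 0.258 (0.231 to 0.287), the inflammation-linked miR-146-5p with 0.259 (0.239 to 0.281) and miR-139-5p with 0.300 (0.269 to 0.335). With median-of-ratios scaling 0 families were 4-fold apart. Female liver held more miR-148-5p, with a ratio of 2.12 (1.91 to 2.34), miR-19-3p with 1.89 (1.75 to 2.03), miR-101-3p with 1.78 (1.71 to 1.85) and miR-20-5p with 1.75 (1.72 to 1.79). The hepatocyte families were near equal on deposited RPM, miR-194-5p with 1.01 (1.01 to 1.02) and miR-122-5p with 0.906 (0.893 to 0.920), which median-of-ratios scaling moved to 1.83 and 1.63. Of the lists, germline and gonadal families had a median log2 ratio of 0.37 over 6 members, of which 3 were higher in female liver, at percentile 95.6 of the random lists, and blood cell families one of -0.31 over 3 members, at percentile 54.9.

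Ovary and testis had the smallest share of families within 2-fold, 21 of 44 (47.7%). Testis held 601 RPM of miR-7-5p, a miRNA of neurons and endocrine cells, against 20.2 RPM in ovary, a testis-to-ovary ratio of 29.8 (95% counting interval 27.2 to 32.8). Testis was also higher in the Hox cluster miRNA miR-10-5p, by 3.06 (2.79 to 3.36), and in miR-29-3p, by 2.23 (2.17 to 2.30). Ovary was higher in the red cell miRNA miR-451-5p, by 7.22 (6.45 to 8.10), in miR-146-5p by 5.75 (5.46 to 6.05), in miR-25-3p by 5.62 (5.19 to 6.10), in miR-30-5p by 5.61 (5.01 to 6.30) and in miR-23-3p by 5.53 (5.26 to 5.83), and at least 5.77-fold in miR-223-3p, which was unlisted in testis. Both arms of miR-202 were higher in ovary, miR-202-3p by 4.55 (4.29 to 4.83) and miR-202-5p by 1.82 (1.79 to 1.84), the latter moving to 0.971 with median-of-ratios scaling. The 4 blood cell families had a median log2 ratio of 2.34, at percentile 99.3 of the random lists, and all 4 were higher in ovary on deposited RPM, while the ratio of miR-142-3p turned from 1.35 to 0.876 after scaling to miRNA reads and to 0.721 with median-of-ratios scaling. Of the 44 families 9 were at least 4-fold higher in ovary and 1 in testis. After scaling to miRNA reads 1 was at least 4-fold higher in ovary and 2 in testis, and with median-of-ratios scaling 0 and 3; the testis-to-ovary ratio of miR-7-5p was 45.8 on the former scale. With 1 library per sex and organ these ratios have no replicate check, and their intervals cover counting error only.

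**Figure D4:**
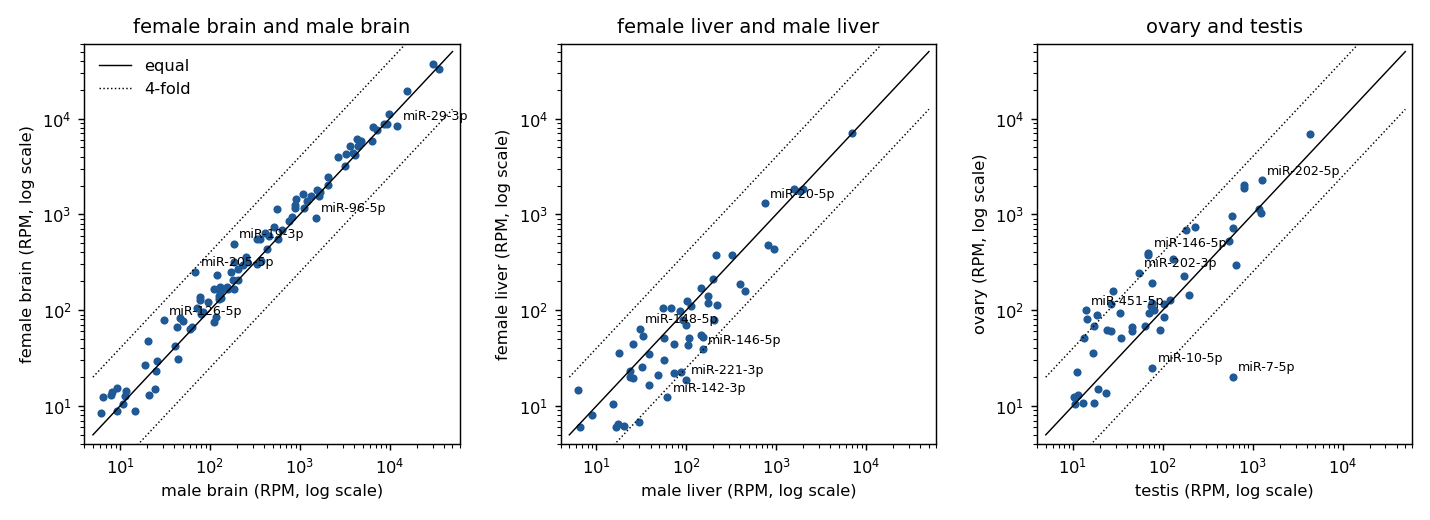
RPM of each listed miRNA family in the female library (y axis, log scale) and the male library (x axis, log scale) of brain, liver and gonads; each point is 1 family, the solid line marks equal values and the dotted lines a 4-fold difference. Of the families with at least 50 RPM in the higher library, 77 of 81 lie within 2-fold in brain, 24 of 38 in liver and 21 of 44 in the gonads, where miR-7-5p lies farthest from the line (601 RPM in testis and 20.2 RPM in ovary).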

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

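The 3 tests of the brain-wide excess of miRNA, the test from the copy with an uncalled base and both tests of T at position 1 were chosen only after the result was seen, and the measure and bound of the variant test and the set of sequences behind the uncalled share were changed then.

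Deposited miRNA values were higher in brain than elsewhere across most families. A smaller library total in brain is argued against, since the mean implied total of the brain libraries was 0.998 times that of the others. A few families taking the miRNA reads are argued against as well: over the 42 families above the minimum in all 4 brain and liver libraries the median log2 fold was 2.25, and 40 of them were higher in brain. These sums leave out forms under the listing minimum, which can raise the folds, as brain listed 929 and 900 miRNA sequences against 171 to 248 elsewhere. With the highest sequence of each family, limma still called 75 of 104 families higher in brain than in liver and 6 lower. Other small RNA filling the liver and gonad libraries could lower their miRNA values, but listed tRNA and rRNA fragments, without 5S rRNA, were only 1.43 times as high there (1636 to 2779.8 RPM against 1326 to 1822 RPM), and since the listed sequences hold only a small part of those libraries this cannot be told apart from the organ. A difference in miRNA content between organs stays open and was not tested.

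The most abundant miR-29-3p sequence of male brain, with 5976 RPM, had no row used from female brain, which lowers the female-to-male ratio of miR-29-3p. A variant carried by the female fish is argued against: of the 5 listed sequences a substitution away, the one above 300 RPM in female brain had a female-to-male ratio of 1.28 (6306 against 4941 RPM), where the mark set beforehand was over 10. The bound first written against it, no such sequence above 300 RPM, was wrong because this other family member is listed in both sexes, and the bound of 2 on the ratio that replaced it was set after these values were seen. The reads may be present in that library all the same: the copy of the sequence with an uncalled base, at 60.1 RPM in female brain, would come from 7548 RPM at the median uncalled share of 0.796% over 44 sequences (6757 to 22802 RPM over the range of shares). The 4 rare sequences a substitution away, 3 of them listed in each sex, had a summed female-to-male ratio of 1.15 (79.1 and 68.8 RPM), but 59.7 and 55.2 RPM of this was a form with another last base, which can be an isoform, and that these are miscalled copies was not tested.

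In the gonads 140 unassigned sequences were listed that brain and liver did not list, 75 in each gonad and 10 of them in both, with 1759.6 RPM in ovary and 1248 RPM in testis. These may be piRNA-like, a germline class of small RNA that tends to start with T in DNA letters. Of their 106 groups of overlapping sequences 87 started with T (82.1%), against 41 of 113 groups (36.3%) of unassigned sequences seen only in brain or liver (Fisher's exact test, two-sided, p = 3.29e-12). An A at position 10, the mark of piRNA made by amplification, was present in 33 of 106 groups (31.1%) against 32 of 113 (28.3%; Fisher's exact test, two-sided, p = 0.66), which leaves that part undecided. Among the 140, 15 sequences were within 4 mismatches of rRNA, 5S rRNA or tRNA references (447 RPM in ovary, 216.03 of it from the 5' end of 5S rRNA, and 10.5 RPM in testis). With such sequences left out of both sets, 85 of 102 groups (83.3%) started with T against 36 of 106 (33.96%). The p-value was 2.43e-13 (Fisher's exact test, two-sided), which argues against the matched fragments as the source of the excess. Fragments of tRNAs without a reference may remain in both sets. The piRNA class itself, mostly longer than 23 nt, was not measured, and other degraded RNA, such unmatched tRNA fragments included, stays open. So do miRNAs missing from the hand-written list, which a T at position 1 would not tell apart from piRNA.

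The female-to-male ratio of miR-221-3p pointed in opposite directions in brain, where it was 1.504, and in liver, where it was 0.191. Scaled to miRNA reads these were 1.37 and 0.207, and with median-of-ratios scaling 1.17 and 0.344, so that brain fell under the bound of 1.5 on both scales. It was the family among 32 compared in both organs with a ratio of at least 1.5 one way and the other, a bound chosen after the values were seen, and the difference between the organs was not tested.

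Sequences outside the miRNA comparisons were present in every library. Adapter sequence held 256 RPM in female brain, 2677 in female liver, 1355 in ovary, 211 in male brain, 1263 in male liver and 198 in testis. Fragments of rRNA, 5S rRNA not counted, held 879 RPM in female brain, 1598 in female liver, 185 in ovary, 553 in male brain, 1152 in male liver and 829 in testis. Fragments of tRNA held 942 RPM in female brain, 985 in female liver, 1451 in ovary, 773 in male brain, 827 in male liver and 1951 in testis. Unassigned sequences, which include the 5S rRNA fragments (294 RPM in ovary), held 6619.8 RPM in female brain, 1667 in female liver, 2919.9 in ovary, 5087 in male brain, 1910.1 in male liver and 2533 in testis.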

How the results depend on the processing

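Scaling to the total of miRNA reads, unlisted values at 0, the filters on 2 or on every library, leaving out the miR-29-3p sequence, exact references, exact sequences and detection at the common minimum were chosen after seeing the data. Over 121 results and 1611 alternative values, 1328 kept direction and side of the threshold or stayed within their error, 75 missed the threshold, 6 passed it, 6 reversed and the rest moved; the cause was not tested except where families left the test. The listing minimum of the files, 10.03 RPM at the highest or 256 reads, limits detection rather than the depth, and the spread rests on 2 libraries per organ.

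With median-of-ratios scaling brain and liver gave 37 families higher and 11 lower in brain, gonads and brain 14 higher and 34 lower in gonads, and the 4-fold counts were 0 lower in female liver and 0 higher and 3 lower in ovary. Scaled to miRNA reads these were 31 and 23, 22 and 26, with 1 higher and 2 lower in ovary, and 14 families enriched in brain (lowered in part by the raised minimum), 5 in liver, 6 in both gonads and 0 in ovary. Without the most abundant families they were 26 and 27, 18 and 23, and 1 and 2. miR-101-3p, 2.34 between brain and liver, reversed to -0.41, -1.19 and -1.55 on these 3 scales in turn, and let-7-5p between gonads and brain to 0.91 on the miRNA scale. The ratio of miR-29-3p between female and male brain reversed to 1.35 without the sequence and to 1.28 with the highest sequence.

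With only families above the minimum in every library, which are fewer, brain and liver gave 36 and 1, gonads and brain 1 and 24, gonads and liver 2 and 0 by limma (9 at an unadjusted p under 0.05). Exact sequences, which are more, gave 608 and 41, 34 and 629, and 39 and 26. With the highest sequence of each family 5 were lower in gonads than liver, 4 were 4-fold higher in ovary, and 2, 1 and 2 were enriched in liver, ovary and both gonads. At 200 RPM 0 were lower in female liver, 3 higher in ovary, and 2, 1 and 2 enriched in liver, ovary and both gonads. With RPM + 10 these 4-fold counts were 0 and 4, and a limma fit of ovary against testis gave 8 higher and 4 lower in ovary on deposited RPM, 7 and 7 scaled to miRNA reads, 3 and 6 with median-of-ratios scaling, 12 and 4 with unlisted values at 0, and 0 and 0 with only families above the minimum in every library (8 at an unadjusted p under 0.05). Its spread is that between the sexes of brain and liver, which says nothing of the spread between gonad libraries, so these counts have no replicate check. At 10-fold 32, 2, 0 and 1 were enriched in brain, liver, ovary and both gonads.

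Leaving out each library in turn gave 54 to 68 higher and 4 to 7 lower in brain than liver, 4 to 8 higher and 61 to 71 lower in gonads than brain, and 8 to 16 higher and 4 to 10 lower in gonads than liver; the lone library left is assumed to vary like the others. Without female brain 4 were higher in gonads than brain and 5 lower than liver, without male brain 4 lower than liver. With sex as a block the counts were 79 and 7, 7 and 74, and 11 and 7; between brain and liver miR-200-3p was lost and miR-19-3p, miR-148-3p and miR-365-3p gained, between gonads and brain miR-7-5p lost and miR-17-5p gained, and between gonads and liver miR-199-5p lost. The sex test gave 0 by limma in each of 12 settings, with 2 at an unadjusted p under 0.05 on deposited RPM and 3 scaled to miRNA reads; without a library it has no residual degree of freedom. Tests of counts with other tools, total counts alone and thinning to the smallest total were not run, because the files hold RPM above a minimum.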

Other observations

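The test of the 5S rRNA hypothesis was chosen only after the result was seen, and the shares by list were computed then.

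Each organ gave its miRNA reads to different lists. Neuronal families held 47.2% of miRNA reads in female brain and 46.5% in male brain, against 0.73% and 1.36% in female and male liver, 2.19% in ovary and 5.62% in testis. Hepatic and gut families held 52.1% in female liver and 47.8% in male liver, and 0.76% to 1.06% in the other libraries. In the gonads let-7 held 29.2% in ovary and 28.7% in testis, against 16.3% and 14.6% in female and male brain and 10.2% and 7.96% in female and male liver. Germline and gonadal families held 16.2% in ovary and 15.3% in testis, against 5.46% and 7.39% in brain and 10.6% and 9.29% in liver, and the pancreas list, through miR-216-5p and miR-217-5p, 5.40% and 8.99%, near its shares of 5.17% and 5.98% in female and male brain. Of the germline list's 3808 RPM in ovary, 2280 were miR-202-5p and 245 miR-202-3p. In testis these arms held 1256 and 53.8 of its 2332 RPM, so the list's share in the gonads was mostly miR-202. Of the same list's 12609 RPM in female brain 8447 were miR-29-3p. No row of its most abundant male brain sequence was used there, so 5.46% may be too low. Endothelium and vascular smooth muscle, mainly miR-143-3p and miR-145-5p, held 7.12% in ovary and 12.3% in testis, against 0.36% to 1.06% in brain and liver.

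Fragments of 5S rRNA, a ribosomal RNA that fish and frogs are known to make from separate oocyte and somatic gene sets, numbered 13 sequences over the 6 libraries and summed to 294 RPM in ovary and to 17.9 to 115 RPM in the other libraries. Those from the 5' end held 216.03 RPM in ovary and were unlisted elsewhere, led by AGCTTACGGCCACACCGCCCTG with 108 RPM. A hypothesis is that ovary may carry a 5S rRNA form of its own, as an oocyte-type gene set would give. In its test, 100% of the 31.8 RPM of 3' end fragments in ovary were in forms that the other 5 libraries did not list; against the form GAATACCAGGTGCTGTAAGTT of other libraries the ovary form was GAATACCAGATGCTGTAAGTT, G10A counted from 1 at the 5' end. The match allowed 4 mismatches to 2 hand-written references, human and Xenopus somatic 5S rRNA, at which 0 of 10000 random sequences matched. The 5' end fragments had 3 mismatches to the Xenopus somatic reference and the middle fragments of ovary (46.1 RPM) 0 to the human one, and no oocyte-type reference was compared. With few reads, 1 ovary library and no genome of the species used, this stays a hypothesis.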
